A study of Mus musculus with 2 samples.

How the data were processed

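Gene expression was measured by polyA plus RNA-seq in mouse bone marrow-derived macrophages, primary phagocytes grown from the marrow of C57BL/6J mice. The 2 libraries form 1 group and are given as biological replicates 1 and 2 in the labels. Both carry a single donor identifier, and nothing in the labels says that they came from separate animals, so the spread between them may be partly technical. Per the labels, cells were exposed to 100 ng/ml lipid A for 12 h, washed for 12 h, and exposed again to 100 ng/ml lipid A for 120 min. Lipid A is the membrane anchor of bacterial lipopolysaccharide and a ligand of the TLR4 receptor complex. The labels do not name the agent uniformly: one field says lipid A and others say lipoprotein A. The former is used here because the description of the experiment gives it. Libraries were made from 1 µg of RNA with a size range of 250 to 400, per the labels. The molecule field names total RNA while the assay field names polyA plus RNA. No unstimulated or singly stimulated sample was analysed here, so no condition was compared with another.

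For each library 3 tables were used. Per the notes deposited with each sample, values refer to the mouse genome build mm10 and the GENCODE M21 annotation, and the gene and transcript tables came from alignments to the transcriptome. The deposited gene table gives expected counts, estimated reads per gene that need not be whole. The deposited TPM values are transcript abundances corrected for length and scaled to a fixed total over every feature in the table, and the deposited FPKM values are fragments per kilobase scaled to mapped fragments. The deposited transcript table also gives the percent of a gene's abundance in each transcript. A second deposited transcript table with estimated counts and TPM was made directly from the reads and an index, without an alignment file, and was summed to genes as an alternative quantification. Program names and versions are not given in the sources used here. Whether counting used strand is not given either, so reads of overlapping or antisense genes are treated as uncertain.

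The gene table had 81881 rows, of which 55536 were annotated genes, 26248 were tRNA rows and 96 were ERCC spike-in controls. All 55536 gene identifiers matched the annotation. Of the annotated genes, 86 had no value in the second quantification and were set to 0 there. Rows for tRNAs, spike-ins and the phiX control genome stayed out of the tests. The phiX rows held 0.0788% of expected counts in replicate 1 and 0.0771% in replicate 2. Total expected counts were 45377715 in replicate 1 and 32112416 in replicate 2. A floor of 3 reads corresponds to 0.0661 and 0.0934 CPM. Intervals and floors cover counting error only, since amplified reads are not independent molecules.

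Levels are TPM with the mean ± SD of 2 libraries. A gene was called detected at a TPM of at least 1 in both. For 37 gene lists, members at a TPM of at least 10 in both libraries were counted, and the median over members of the mean log2(TPM + 1) was ranked among 10000 random lists of protein-coding genes of the same size. Lists held 559 symbols in all, with the key genes and isoform genes included, and 557 were measured. Ratios of replicate 2 to replicate 1 used expected counts, a prior of 0.5 reads and TMM-scaled library sizes from edgeR 4.0.16, for the 12552 genes with a mean expected count of at least 10. The median log2 ratio of a list was ranked among 10000 random lists matched on mean expression in 50 bins, and lists outside the central 95% of them were named. Lists with fewer than 3 tested members got no such rank. An exact two-sided binomial test on rounded counts compared the libraries gene by gene, with Benjamini-Hochberg adjustment and a threshold of 0.05. For genes with over 20000 reads its p was 2 times the smaller exact tail. This test compares 2 libraries, not conditions. Dispersion came from an intercept-only edgeR fit. Isoform shares are a transcript's deposited TPM as a percent of its gene's TPM.

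Gene lists, the main thresholds and the rule for named genes were fixed before the data were examined. The rule names the key genes, the 4 members of each list with the highest mean TPM, with members under 1 TPM in both libraries given as a count, the 10 genes with the highest mean TPM, the 5 genes highest in each replicate by ratio among those with a mean expected count of at least 100, and up to 12 isoform genes whose leading transcript is under 90% in either library. The tiers of 100 and 1000 TPM, the block of mitochondrial pseudogenes and genes named for disagreement between quantifications were chosen after values were seen. Other genes named in the text to explain a list or an overlap were also chosen after values were seen.

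Alternatives were DESeq2 1.42.0 size factors, library totals, ratios of TPM with a pseudocount of 0.01, other count filters, levels of 0.5, 5 and 20 TPM, a pseudocount of 0.1, FPKM, the second quantification, TPM rescaled to nuclear protein-coding genes, random lists from detected genes, and each library alone. Scaling by nuclear protein-coding genes divided the TPM of each gene by their total, a definition settled after values were seen. Added after seeing the data were removal of a smooth trend on GC content and log transcript length, exclusion of mitochondrial genes and their pseudogenes, and protein-coding genes alone. GC content and length came from the leading transcript of 12544 of 12552 genes. Gene-bootstrap intervals used 500 draws.

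The steps were tested on simulated data. With no biological variation, the binomial test called 98.0% of 196 genes changed 4-fold and 0.0566% of unchanged genes, over 12573 genes. With a simulated biological coefficient of variation of 0.2 it called 57.8% of unchanged genes, over 12563 genes, and with 0.4 it called 73.7%, over 12509 genes. Its calls therefore describe these libraries only. The dispersion fit returned coefficients of 0.121, 0.23 and 0.408 for simulated values of 0, 0.2 and 0.4. The genes changed 4-fold were left in this fit and add to its spread. Whether the fit itself overstates low values can therefore not be told from these figures. Of 100 random lists of 20 genes, 3 fell outside the central range, and all 100 did so after being raised by 1 on the log2 scale. Over 9696 genes with a planted trend, trend removal lowered the SD of the log2 ratio from 0.88 to 0.63, which was also the SD before planting. After removal the SD was 0.62718 with and without planting, so the planted trend had a shape that the fit can take exactly. Removal of trends of other shapes was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.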

Results

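Transcript levels were measured in 2 replicate libraries of bone marrow-derived macrophages given lipid A, washed, given lipid A again and taken 120 min into the second exposure. The data describe the levels that genes of the inflammatory response held at this point. Replicate 1 had 45377715 expected counts and replicate 2 had 32112416. A TPM of at least 1 in both libraries was reached by 10468 genes, of which 9773 were protein coding, and a further 425 genes reached it in replicate 1 alone and 407 in replicate 2 alone. Protein-coding genes held 94.4% and 95.5% of expected counts.

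The highest level was that of Fth1, the ferritin heavy chain, with 45260 ± 2076 TPM (SD, n = 2), and Ftl1, the ferritin light chain, stood at 14299 ± 4482 TPM. B2m, the light chain of MHC class I, was at 15825 ± 3079 TPM. The chemokine Ccl5 was at 15155 ± 5648 TPM and the acute phase gene Saa3 at 14633 ± 9378 TPM. Tmsb4x, which binds actin monomers, was at 10670.5 ± 4270.5 TPM, and Psap, the precursor of lysosomal saposins, at 10069 ± 1218 TPM. The mitochondrial genes mt-Atp8 and mt-Co1 were at 27490 ± 15242 and 9869 ± 5922 TPM, but mt-Atp8 had 16712 and 38267 TPM here against 4453 and 7719 in the second quantification. The ribosomal RNA gene CT010467.1 was at 30858 ± 8265 TPM and rRNA held 3.97% of counts in replicate 1 and 2.60% in replicate 2. The 20 genes with the most counts held 19.2% of them in replicate 1 (exact 95% interval 19.2 to 19.2%) and 17.5% in replicate 2 (17.5 to 17.5%).

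Inflammatory cytokine transcripts were present over a wide range. Of 24 measured cytokines, 16 reached 10 TPM in both libraries, 8 reached 100 TPM and 5 were under 1 TPM in both. Tnf (chromosome 17, 35199381 to 35202007) was at 1131 ± 75.1 TPM, with 1078 in replicate 1 and 1184 in replicate 2. Il1b was at 842 ± 337 TPM, Il1a at 743 ± 348 TPM and Ebi3, a subunit of interleukin 27, at 355 ± 32.6 TPM. Il6 (chromosome 5, 30013114 to 30019981) was far lower and less even, with 10.7 TPM in replicate 1 and 36.3 TPM in replicate 2. Il12b, the p40 chain of interleukin 12 (chromosome 11, 44400063 to 44414033), was at 34.9 and 159 TPM. The anti-inflammatory cytokine Il10 was close in both, at 13.6 and 15.5 TPM.

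Of 22 chemokines 14 reached 10 TPM in both libraries, and after Ccl5 came Cxcl10 at 2731 ± 121 TPM, Ccl4 at 2205 ± 635 TPM and Ccl3 at 1966 ± 165 TPM. All 40 interferon-stimulated genes reached 10 TPM in both libraries and 35 reached 100 TPM. Irf7 was at 2000.2 ± 44.0 TPM, Isg15 at 1853 ± 461 TPM, Ifit2 at 1421 ± 84.2 TPM and Bst2 at 1401 ± 847 TPM. Of 9 interferon genes, Ifnb1 alone reached 10 TPM, at 13.7 and 14.6 TPM, and 8 were under 1 TPM in both libraries, with Ifng at 0.39 ± 0.48 TPM.

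Genes of the receptor pathway and of its inhibitors were both expressed. Of 24 TLR4 pathway components 20 reached 10 TPM in both libraries, led by the coreceptor Cd14 at 690 ± 301 TPM, with Ikbke at 232 ± 11.3 TPM, Irf5 at 214 ± 8.59 TPM and Irak2 at 212 ± 81.5 TPM. Tlr4 itself (chromosome 4, 66827584 to 66930284) was at 21.3 and 13.0 TPM. In the NF-kB list 10 of 11 members reached 10 TPM, among them Nfkbia, the inhibitor IkBα, at 627 ± 24.8 TPM, Nfkbiz at 254 ± 113 TPM, Rela at 225 ± 170 TPM and Nfkb1 at 211 ± 40.3 TPM. Of 28 negative regulators 22 reached 10 TPM. Tnip3 was at 541 ± 118 TPM, Atf3 at 463 ± 180 TPM and Ptpn6 at 393 ± 21.4 TPM. The deubiquitinase Tnfaip3 was at 236 ± 50.5 TPM, Socs3 at 223 ± 13.5 TPM, Il1rn, the interleukin 1 receptor antagonist, at 305 ± 36.7 TPM and Irak3 at 87.0 ± 36.7 TPM. Of 23 immediate early transcription factors 12 reached 10 TPM, with Klf6 at 354 ± 107 TPM, Junb at 208 ± 33.2 TPM, Egr1 at 153 ± 113 TPM and Jund at 99.9 ± 17.2 TPM.

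Antimicrobial and metabolic effectors differed in level. Of 20 antimicrobial and acute phase genes 11 reached 10 TPM in both libraries. Besides Saa3, lysozyme Lyz2 was at 9397 ± 591 TPM, Acod1, which makes itaconate, at 4199 ± 1630 TPM and Cyba at 1530 ± 834 TPM. Lcn2 was at 69.6 ± 37.4 TPM and Camp at 0.25 ± 0.21 TPM. The inducible nitric oxide synthase Nos2 was at 16.9 and 45.9 TPM, while Arg1 had 4 reads in replicate 1 and 0 in replicate 2. Of 15 arginine and prostaglandin enzymes 10 reached 10 TPM, with Alox5ap at 209 ± 1.01 TPM, Ptgs2 at 87.4 ± 42.9 TPM, Hpgds at 74.4 ± 21.5 TPM and Gch1 at 39.3 ± 7.28 TPM. Of 19 glycolysis genes 15 did so, with Gapdh at 1959 ± 282 TPM, Pkm at 555 ± 16.3 TPM, Aldoa at 553 ± 67.8 TPM and Ldha at 346 ± 36.1 TPM. Of 15 oxidative stress genes 12 did so, including Sqstm1 at 1761 ± 1128 TPM, Prdx1 at 1095 ± 134 TPM, Sod2 at 888 ± 34.8 TPM and Hmox1 at 378 ± 55.2 TPM. Endoplasmic reticulum and amino acid stress genes reached 10 TPM in 11 of 12 cases, with Hspa5 at 459 ± 55.4 TPM, Ddit3 at 248 ± 53.6 TPM, Atf4 at 128 ± 3.01 TPM and Ppp1r15a at 103 ± 33.99 TPM. Heat shock genes did so in 10 of 11, with Hspa8 at 2337 ± 868 TPM, Hsp90ab1 at 839.9 ± 148 TPM, Hspe1 at 142 ± 9.17 TPM and Hsp90aa1 at 115 ± 2.43 TPM.

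Macrophage marker genes had high levels. Of 20 macrophage identity genes 19 reached 10 TPM in both libraries, with the lysosomal proteases Ctsd at 8385 ± 1217 TPM, Ctsb at 7330 ± 2409 TPM and Ctss at 3505 ± 374 TPM, and Fcer1g at 4023 ± 210 TPM. Of 21 pattern recognition and scavenger receptors 20 did so, with Clec4e at 929 ± 297 TPM, Marco at 413 ± 150 TPM, Tlr2 at 389 ± 29.0 TPM and Msr1 at 286 ± 22.5 TPM. The formyl peptide receptor Fpr1 was at 138 ± 10.6 TPM. Antigen presentation genes did so in 19 of 20 cases, with B2m followed by H2-K1 at 8963 ± 1105 TPM, H2-D1 at 4973 ± 803 TPM and Cd74 at 761 ± 348 TPM. Inflammasome and cell death genes did so in 21 of 23, with Bcl2a1b at 568 ± 108 TPM, Mcl1 at 388 ± 25.3 TPM, Gadd45b at 373 ± 46.1 TPM and Bcl2a1d at 366 ± 24.4 TPM. Bcl2a1b and Bcl2a1d are near-identical copies, so their separate levels are uncertain. Cholesterol and lipid genes did so in 18 of 20, with Apoe at 6887 ± 2429 TPM, Plin2 at 605 ± 319 TPM, Soat1 at 274 ± 16.3 TPM and Acsl1 at 169 ± 104 TPM. Only 4 of 14 alternative activation genes did so, namely Il4ra at 121 ± 19.5 TPM, Stab1 at 81.7 ± 38.9 TPM, Mrc1 at 34.6 ± 4.88 TPM and Folr2 at 33.8 ± 14.7 TPM, and 6 were under 1 TPM in both. All 12 housekeeping genes reached 10 TPM, with Actb at 6822 ± 485 TPM, Eef1a1 at 3020.01 ± 168 TPM and Ppia, which has many processed copies, at 1110.1 ± 228 TPM. Of 21 cell cycle genes 8 did so, with the inhibitor Cdkn1a at 828 ± 220 TPM, Pcna at 210.5 ± 11.9 TPM, Mcm6 at 33.9 ± 0.42 TPM and the proliferation marker Mki67 at 15.5 and 48.4 TPM.

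Many markers of other cell types were under 1 TPM in both libraries: 9 of 11 T cell markers, 7 of 9 B cell markers, 6 of 8 NK cell markers, 7 of 10 dendritic cell markers, 9 of 10 mast cell and basophil markers, 8 of 9 erythroid markers, 5 of 8 megakaryocyte and platelet markers, all 11 stromal markers, 4 of 8 endothelial markers, 4 of 9 osteoclast markers and 8 of 15 neutrophil markers. The exceptions with the highest levels were Pf4 at 183 ± 124 TPM, Csf3r at 139 ± 29.0 TPM, Cd4 at 56.0 ± 5.35 TPM, Acp5 at 54.8 ± 25.9 TPM and Cd28 at 34.4 ± 1.46 TPM, followed by S100a8 at 14.7 ± 15.6 TPM, Nfatc1 at 13.9 ± 2.13 TPM, S100a9 at 13.8 ± 17.8 TPM and Atp6v0d2 at 12.9 ± 2.17 TPM. Others included Kdr at 9.43 ± 6.87 TPM, Hdc at 6.10 ± 1.26 TPM, Mmp8 at 5.67 ± 0.18 TPM, Cd79b at 4.89 ± 3.42 TPM, Batf3 at 4.78 ± 3.44 TPM and Klrk1 at 4.31 ± 3.98 TPM. Among replication-dependent histones 7 of 10 were under 1 TPM, while Hist1h2bc was at 211 ± 78.9 TPM, Hist1h1c at 87.7 ± 11.4 TPM and Hist1h4i at 11.3 ± 1.60 TPM. Of 5 nuclear long noncoding RNAs 3 reached 10 TPM, with Malat1 at 733 ± 353 TPM, Gas5 at 101 ± 35.3 TPM and Neat1 at 91.9 ± 50.5 TPM, and Snhg1 was at 11.5 ± 5.37 TPM. Of 6 sex-linked genes 5 were under 1 TPM, with Xist at 71.5 ± 32.3 TPM and Ddx3y and Eif2s3y on the Y chromosome at 0 reads in both libraries, which allows up to 0.0661 and 0.0934 CPM. All 13 mitochondrially encoded genes reached 10 TPM, with mt-Nd6 at 2298 ± 969 TPM and mt-Nd1 at 2057 ± 908 TPM.

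By rank, 21 of the 37 lists had a median level above the central 95% of random protein-coding lists, and none lay below it. Some lists could not have ranked below it. Interferons, erythroid markers and sex-linked genes had a median of 0, the lowest possible, yet ranked at 10.5, 10.6 and 7.1. Many random lists also had a median of 0, and ties were ranked at their middle. The 21 lists above the range included cytokines, chemokines, interferon-stimulated genes, macrophage identity and negative regulators. Against random lists of detected genes, 6 of the 21 were no longer above it, among them TLR4 pathway components at 90.2 and immediate early factors at 43.2.

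**Figure D1:**
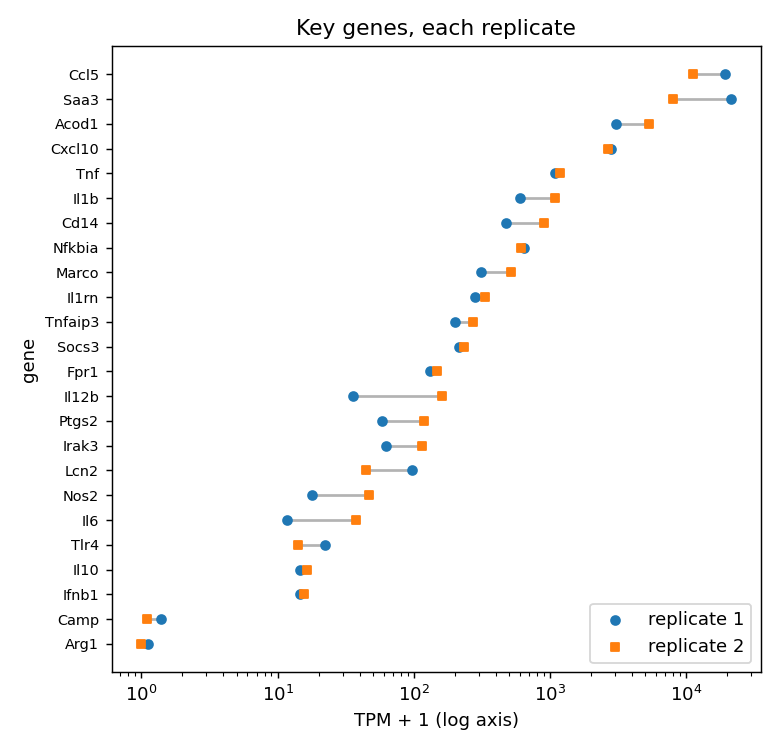
Level of each of the 24 key genes in replicate 1 (circles) and replicate 2 (squares), as TPM + 1 on a log axis, with a grey line joining the replicates. Tnf lies at 1078 and 1184 TPM, while Il12b lies at 34.9 and 159 TPM.

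The replicates were compared with each other to show how much spread each level carries. Across 55536 genes, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.987 and TPM a Spearman rho of 0.919, and over the 12552 genes with a mean of at least 10 reads r was 0.970. The log2 ratio between libraries had an SD of 0.79 and a median size of 0.36, a 1.29-fold difference. A ratio of at least 2-fold was seen in 1417 genes (11.3%), 753 higher in replicate 1 and 664 in replicate 2, falling to 636 among the 9702 genes with at least 100 reads. The exact binomial test, which allows for counting noise only, called 8184 genes, 4080 higher in replicate 1 and 4104 in replicate 2, and the chi-square per degree of freedom was 177. The edgeR common biological coefficient of variation was 0.292.

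**Figure D2:**
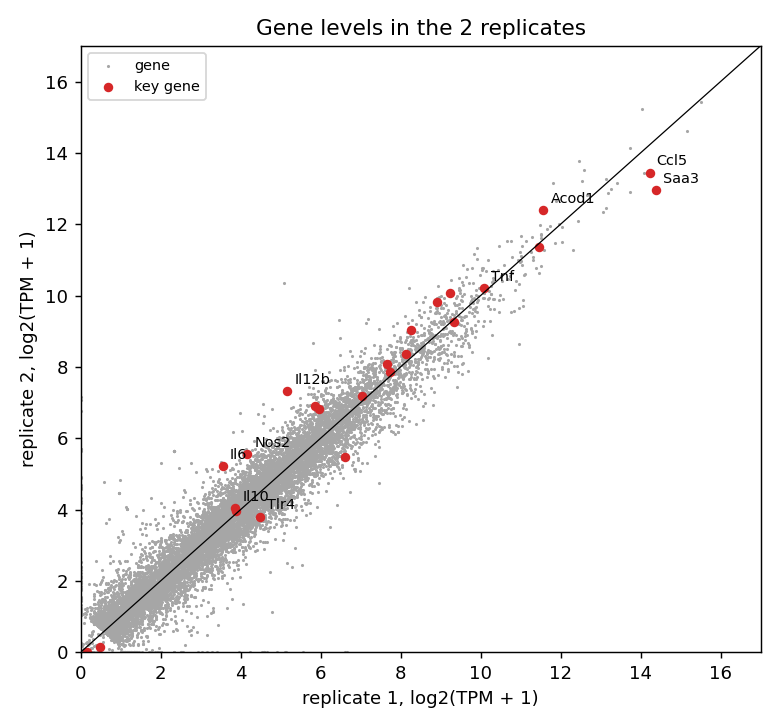
Each grey point is a gene, with log2(TPM + 1) in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis, for genes with a mean TPM of at least 0.5 and all listed genes. Red points are the key genes and the line marks equal levels. Il6 at 10.7 and 36.3 TPM lies above the line and Saa3 at 21265 and 8002 TPM below it.

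Several inflammatory groups had a higher median in replicate 2. Inflammatory cytokines had a median log2 ratio of 0.87 over 21 tested members, 18 of them higher in replicate 2. Over all genes the exact binomial test called 18 of them, 15 in that direction, and 20 when adjusted over the list alone. Il12b was 4.61-fold, Il6 3.40-fold and Il1b 1.82-fold higher in replicate 2, while Tnf differed 1.11-fold. Without the 4 members under a mean of 100 reads the median was 0.21, at a percentile of 93.0 and inside the range of random lists, although 14 of the 17 left were higher in replicate 2 and 6 at least 2-fold. NF-kB genes had a median of 0.49 (9 of 11 higher in replicate 2), oxidative stress genes 0.52 (11 of 15), endoplasmic reticulum and amino acid stress genes 0.49 (10 of 12), immediate early factors 0.45 (14 of 22), heat shock genes 0.40 (7 of 10) and negative regulators 0.23 (20 of 28). In that order, the members called over all genes as higher in replicate 2 numbered 9, 11, 9, 12, 7 and 18, and as higher in replicate 1 they numbered 2, 4, 2, 8, 1 and 5. Those adjusted over the list alone numbered 11, 15, 12, 20, 8 and 24 in either direction. Immediate early factors (0.15) and negative regulators (0.19) came to lie inside the random range with at least 100 reads. So did NF-kB genes (0.39), endoplasmic reticulum and amino acid stress genes (0.36) and negative regulators (0.25) with the TPM ratio, and heat shock genes (0.33) with a GC and length trend removed, an alternative chosen after seeing the data. Endothelial markers, with 4 tested members, lay at 0.70, barely outside the range, whose upper end was 0.69, with 2 called over all genes, both higher in replicate 2, and 2 adjusted over the list alone. Their median was 1.13 with the TPM ratio and 1.33 with at least 100 reads. Nos2 was 2.73-fold, Ptgs2 2.08-fold, Cd14 1.97-fold, Irak3 1.88-fold, Marco 1.86-fold and Acod1 1.77-fold higher in replicate 2.

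Mitochondrially encoded transcripts were also higher in replicate 2, with a median log2 ratio of 0.96 and 11 of 13 members higher there. All 13 were called over all genes, 2 of them higher in replicate 1, and 13 adjusted over the list alone. With mitochondrial rRNA included, they held 1.06% of counts in replicate 1 and 2.17% in replicate 2. Single members are uncertain because reads are shared with a block of near-identical pseudogenes on chromosome 1 (24611535 to 24616197). Reads assigned to this block are not part of these shares of counts, which may therefore be too low. There Gm28661, named after its values were seen, had 74124 and 81497 expected counts. In this block Gm10925 had 9063 TPM in replicate 2 in the gene table and 0.0352 TPM in the second quantification.

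Other groups had a higher median in replicate 1. Neutrophil markers had the lowest median, a log2 ratio of -2.71 over 7 tested members, 6 of them higher in replicate 1. It was -1.23 with the TPM ratio and -1.45 in the second quantification. Over all genes 4 members were called higher in replicate 1 and Csf3r in replicate 2, and 5 were called adjusted over the list alone. S100a9 was at 26.4 and 1.18 TPM (194 and 6 reads), S100a8 at 25.8 and 3.72 TPM and Ngp at 7.99 and 0.40 TPM (235 and 8 reads). Megakaryocyte and platelet markers had a median of -1.47 over 5 members, with 3 called over all genes higher in replicate 1 and 1 in replicate 2, and 4 adjusted over the list alone. Among them were Pf4 at 271 and 95.2 TPM, Ppbp at 2.83 and 0.58 TPM, and Vwf in the other direction. Alternative activation genes had a median of -0.63 (7 of 11 higher in replicate 1) and cell cycle genes -0.47 (17 of 21), with Mki67 in the other direction. Over all genes, 7 alternative activation genes were called higher in replicate 1 and 2 in replicate 2, and 13 and 4 cell cycle genes. Adjusted over the list alone 9 and 17 were called in either direction. Saa3 was 2.55-fold, Lcn2 2.18-fold, Ccl5 1.65-fold and Tlr4 1.62-fold higher in replicate 1. In all, 13 of 31 lists with at least 3 tested members lay outside the central range of matched random lists, 9 above and 4 below. For lists of randomly drawn genes chance gives 1.55. Genes of a named list may vary together, unlike randomly drawn genes, so that figure may be too low here. The lists share members, so their results are not independent. Inside the central range lay interferon-stimulated genes (0.06), chemokines (-0.01), TLR4 pathway components (0.15), antimicrobial genes (-0.19), pattern recognition receptors (0.17), arginine and prostaglandin enzymes (-0.13), glycolysis (-0.07), macrophage identity (-0.23), antigen presentation (0.10), inflammasome and cell death (-0.08), cholesterol and lipid genes (0.01) and housekeeping genes (-0.04). So did T cell (0.10), dendritic cell (-0.32), stromal (0.43) and osteoclast (-0.19) markers, histones (0.55) and nuclear long noncoding RNAs (-0.63). Antimicrobial genes, macrophage identity and nuclear long noncoding RNAs lay outside it with the TPM ratio, at -0.41, -0.30 and -0.73. The other 6 lists had too few tested members.

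**Figure D3:**
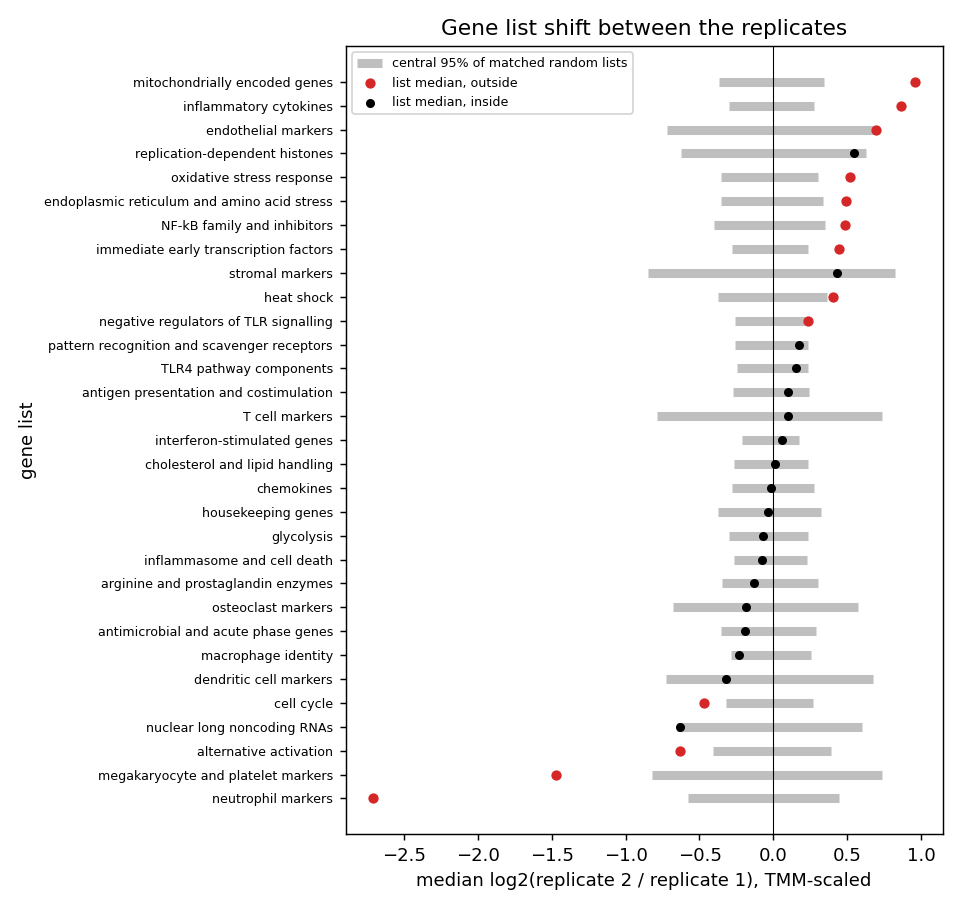
Median log2 ratio of replicate 2 to replicate 1 for 31 gene lists, TMM-scaled, with grey bars for the central 95% of 10000 random lists matched on mean expression. Red points lie outside that range and black points inside it. Neutrophil markers lie at -2.71 and mitochondrially encoded genes at 0.96.

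Among genes with a mean of at least 100 reads, the 5 furthest apart in each direction were examined. Of these 10, 8 overlap another annotated gene and 7 had 0 reads in one library, so the values of those that overlap are uncertain. The exceptions were S100a9, 20.4-fold, and Ngp, 18.9-fold higher in replicate 1. Gm26778, which overlaps Kctd12, had 5069 expected counts in replicate 1 and 0 in replicate 2, at least 1136-fold higher against a floor of 3 reads per library, while the second quantification gave it 5856 and 2783 estimated counts. Gm26669, overlapping Zfp36l1, and Gm47248, overlapping Trim34a, were at least 191-fold and 53.1-fold higher in replicate 1, on counts that were lower in the second quantification, at 353 and 0 for Gm26669 and 71.4 and 0 for Gm47248. Gm28439, in the block of mitochondrial pseudogenes, Gm20425, Gm28037 and Gm11175 were at least 676-fold, 546-fold, 474-fold and 140-fold higher in replicate 2. The second quantification gave Gm28439 0 and 11381 estimated counts, Gm20425 1346 and 1599, Gm28037 10.7 and 1769, and Gm11175 0 and 21.5, so these folds depend on the quantifier. Gm49369, which overlaps Ctsd, had 565 and 15546 expected counts, and 1798 and 24529 in the second quantification.

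Most expressed genes used several annotated transcripts. Of 8865 genes with more than 1 transcript and at least 100 reads, 2547 (28.7%) had a transcript with at least 90% of TPM in both libraries, and 7633 had the same leading transcript in both. Of 28 isoform genes 19 had a leading transcript under 90% in either library. Zbp1 was split between 54.9 ± 0.50% and 44.1 ± 0.54% (SD, n = 2), Tnfaip3 led with 51.4 ± 2.70% and Il1rn with 79.2 ± 1.09%. In Nfkbiz the leading transcript held 62.5 ± 8.71%, in Pkm 71.0 ± 7.94%, in Cflar 72.0 ± 1.49%, in Cd14 86.9 ± 2.83%, in Marco 83.5 ± 5.46% and in Irf7 45.9 ± 4.50%. The second quantification gave 91.9% and 97.7% for Marco, above the 90% line, and 58.4% and 64.4% for Irf7. It moved the leading share by more than 1 SD in 11 of the 28 isoform genes and by less in 17. For Sod2 the leading transcript was annotated as a retained intron, at 44.8 ± 0.22%. A processed transcript of Sod2 held 38.5 ± 1.93% and the protein-coding Sod2-201 held 9.09 ± 0.67%. Most of the Sod2 gene level was thus assigned to transcripts not annotated as protein coding. In Sqstm1 a retained-intron transcript held 0.12% in replicate 1 and 25.1% in replicate 2, and 0.38% and 19.0% in the second quantification. The Cd40 transcript with the highest mean share held 29.9% and 67.3%.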

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

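Reads assigned to the phiX control genome, a sequencing control outside the genes compared here, numbered 35753 in replicate 1 and 24752 in replicate 2, above the 3 reads that a count of 0 allows.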

How the results depend on the processing

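The removal of the GC and length trend, the exclusion of mitochondrial genes and their pseudogenes, and the restriction to protein-coding genes were chosen after seeing the data. No paired analysis was possible because the 2 libraries form a single group. The number of detected genes, the binomial calls and the count of genes with a dominant transcript stayed within 1.5 times under each alternative run for them, at 7814 to 11359, 7261 to 8333 and 2022 to 3249. Of 259 list level counts under alternatives 248 did so too, of 259 level percentiles 253 and of 151 list shifts 136 kept their side of the threshold. Some of these could hardly change. Of the list shifts, 31 used DESeq2 size factors, which move all ratios almost alike. Of the level percentiles, 37 each used FPKM, rescaled TPM and the pseudocount of 0.1, which barely alter the order of genes. Single libraries lie within 1 SD of their mean by construction, and under the other alternatives key gene levels stayed within 1 SD in 48 of 72 and leading isoform shares in 17 of 28. No shift of a list outside the range changed sign, though the neutrophil median of -2.71 was -1.23 with the TPM ratio and -1.45 in the second quantification. Library totals moved the 2-fold split from 753 and 664 to 917 and 573, and the binomial calls from 4080 and 4104 to 4801 and 3532. Causes of the changes below were not tested, except that stricter filters test fewer genes.

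List levels moved as follows. Interferons fell from 1 to 0 with FPKM and at 20 TPM. At 20 TPM, counts were 6 for arginine and prostaglandin enzymes, 5 for cell cycle, 6 for endoplasmic reticulum and amino acid stress and 1 for osteoclast markers, the last also 1 with FPKM. At 5 TPM, neutrophil markers gave 2 and mast cell and basophil markers 1. Single libraries gave 1 to 3 for neutrophil markers and 0 to 1 for endothelial markers. Against random lists of detected genes, level percentiles were 90.2 for TLR4 pathway components, 43.2 for immediate early factors, 83.1 for arginine and prostaglandin enzymes, 84.0 for endoplasmic reticulum and amino acid stress, 80.3 for heat shock and 96.6 for nuclear long noncoding RNAs.

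Pearson r was 0.985 with a pseudocount of 0.1, 0.970 and 0.960 with at least 10 and 100 reads, and 0.982 in the second quantification. The SD of the log2 ratio was 0.97 with no filter, 0.63 with at least 100 reads and 0.84 in the second quantification. Genes 2-fold apart numbered 4409 with no filter and 636 with at least 100 reads.

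With at least 100 reads, list shifts ended inside the random range for inflammatory cytokines (0.21), negative regulators (0.19) and immediate early factors (0.15), and nuclear long noncoding RNAs moved outside it (-0.63). With the TPM ratio, NF-kB genes (0.39), negative regulators (0.25) and endoplasmic reticulum stress genes (0.36) ended inside, and antimicrobial genes (-0.41), macrophage identity (-0.30) and nuclear long noncoding RNAs (-0.73) outside. The latter also lay outside in the second quantification (-0.64). With the GC and length trend removed, heat shock ended inside (0.33), and antimicrobial genes (-0.26), macrophage identity (-0.21) and nuclear long noncoding RNAs (-0.52) outside.

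The share of the top 20 genes was 27.2% of TPM and 32.4% in the second quantification, against 18.3% of counts. The mitochondrial share, rRNA included and the pseudogene block left out, was 5.21% and 3.69%, against 1.62%. With 2 libraries, the SD of each level has a single degree of freedom.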

Other observations

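Of the tests below, those of the second quantification and of library composition were chosen after the result was seen, as were the use of intervals in deciding the tests, the share of genes below which a test decides nothing, and the fitted trends and random lists that settled the trend test of the neutrophil markers. That trend test was first written before its value, as were the remaining tests, though the patterns came from an earlier look at the listed genes. Lcn2 and Hp, already read, were taken out of the second neutrophil list after a run that included them.

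The 2 quantifications of the same reads placed 40 of 9702 genes at least 2-fold higher and 67 at least 2-fold lower in the second, in both libraries. The comparison included a constant log2 offset per library, so some counted genes differ by less than 2-fold in deposited TPM. An example is mt-Nd4l, with 754.5 and 1257 TPM in the gene table against 1372 and 2404 in the second quantification. Malat1 had 61735 and 31990 expected counts, a log2 ratio of -0.38, while its TPM was 484 and 983, so the unit decides its direction. A TPM ratio of at least 2-fold pointed against the count ratio in 21 of 869 genes. These counts were chosen after values were seen.

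Replicate libraries are expected to differ by more than counting noise, and sources of their spread were tested. The log2 ratio was correlated with GC content (Spearman rho -0.27) and with transcript length (0.27), so a trend with both was present. Removing a smooth trend on GC content and transcript length lowered the SD of the log2 ratio by 4.90% (bootstrap interval 3.71 to 6.27%), over genes with at least 100 reads. In the second quantification the percent fall was -8.08% (-19.8 to 1.88%), where a negative fall is a wider spread. Both lie under the 20% set as the limit, which argues against the trend as the main source. The second quantification has assignment errors of its own, so its spread need not fall even where quantification adds spread. That test therefore cannot decide on the quantifier. Leaving out mitochondrial genes and their pseudogenes lowered the SD by 2.12% (0.10 to 5.93%). With 22 of 9702 genes left out the SD could hardly fall, so this decides nothing. Differences between cultures or in library preparation stay open too.

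Inflammatory cytokines had a median log2 ratio of 0.87 between replicates. After removal of the trend on GC content and length 97.7% of it was kept (97.7 to 274%), which argues against that trend as the cause. The cytokine median exceeded that of housekeeping genes by 0.90 (0.09 to 1.33). That interval reaches below the limit of 0.3, so this test could not decide on library composition. A scaling offset from composition would move all genes alike. The TMM scaling itself centres the ratios, so the median of -0.02 over the 12552 tested genes cannot tell of an offset. With library totals that median was -0.09. The 21 tested cytokines had a percentile of 100 among matched random lists, a rank that an offset shared by all genes cannot produce. DESeq2 size factors (0.89) move all ratios almost alike, so the percentile of 100 kept with them was settled in advance. The TPM ratio (0.84) also gave 100. For these 21 members the rank thus argues against a shared offset as the cause. With at least 100 reads the cytokine median was 0.21, inside the range of random lists, so the size of the shift may depend on the 4 members under that count.

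Of 7 tested neutrophil markers, S100a8, S100a9, Ngp and Ltf were called higher in replicate 1, Csf3r in replicate 2 and Mmp8 and Mmp9 in neither, and a candidate explanation for the first 4 is more neutrophil-lineage cells in that culture. In a second list of 28 neutrophil genes, 9 of the 14 tested members not read before were higher in replicate 1, or 64.3% (exact interval 35.1 to 87.2%), between the limits of 50% and 75%, and 11 of 16 (68.8%) with Lcn2 and Hp. Of those 14, 5 reached 10 TPM in both libraries, so macrophages may express them too, and S100a8 and S100a9 were at 25.8 and 26.4 TPM in replicate 1. Removal of the GC and length trend kept 96.4% of the median (46.6 to 336%), and since the trend fitted to the 7 members ran only from -0.13 to 0.11, it is argued against as the cause. Neutrophil cells stay open, but markers of other lineages, chosen after values were seen, were also higher in replicate 1, namely Gzmb (89 and 1 reads), Epor (76 and 4), Klrk1 (227 and 45), Batf3 (96 and 18), Cd79b (216 and 50) and Pf4 (2600 and 631), while Kit (22 and 56), Vwf (344 and 583) and Kdr (808 and 1705) were higher in replicate 2.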
